A study of Caenorhabditis elegans with 40 samples.

How the data were processed

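Whole-body gene expression was measured by RNA sequencing in 40 libraries of Caenorhabditis elegans on day 1 of adulthood. Each library came from 1 of 5 genotypes, which were the wild type strain and the mutants age-1(hx546), clk-1(qm30), eat-2(ad1116) and raga-1(ok386), exposed since hatching to an empty vector or to RNA interference (RNAi) against repo-1. The 10 groups of genotype and treatment held 4 libraries each. Per the labels, total RNA was extracted with a Qiagen miRNeasy kit and libraries were made with Roche Kapa stranded mRNA HyperPrep. The labels number the libraries of a group 1 to 4 and give the same number as the batch. They do not say whether the 4 samples of a group came from separate cultures, so p-values measure the spread between these samples alone.

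The submitters' notes name FastQC 0.11.8, STAR, MultiQC, Salmon 0.14.2 and DESeq2, without their roles, and the genome build WBcel235. The deposited table held 20956 genes, of which 20124 were protein-coding, 612 tRNA genes, 209 pseudogenes and 11 others, and 40 columns, all of which were matched to a library. The deposited unit is a normalized signal, gene counts divided by 1 size factor per library by the authors. Dividing each column by its smallest value above 0 returned whole reads, with 100% of values within 0.01 of a whole number in every column. In 2 columns, clk-1 repo-1 RNAi replicate 1 and age-1 repo-1 RNAi replicate 4, the step was close to 1 and this test carried little information. The recovered totals ranged from 7.43 M reads in eat-2 repo-1 RNAi replicate 3 to 40.8 M reads in eat-2 empty vector replicate 2. Of the gene identifiers, 19897 were in the reference names and 19105 carried the current symbol. The table counts reads per gene, so it holds no splicing measurements, and transcript isoforms were not analysed here. Genes with near-identical paralogs, such as the major sperm protein, nspc, nspd and histone families and the pud-2.1 and pud-2.2 pair, share reads in ways the table does not resolve, and their single-gene values are uncertain.

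Values were analysed as log2 of the deposited value plus 1, for the 12327 genes with a mean of at least 10 over the 40 libraries. One linear model with a mean per group was fitted to all 40 libraries with limma 3.58.1 in R 4.3.3, with an intensity trend. It gave 14 comparisons, which were repo-1 RNAi against empty vector in each genotype and averaged over the 5 genotypes, each mutant against wild type on empty vector, and, for each mutant, the RNAi effect minus that in wild type (the interaction). P-values were adjusted by Benjamini and Hochberg's method within each comparison, and genes with an adjusted p under 0.05 were called. Errors printed after ± are standard errors (SE) of log2 fold changes from this model unless they are named standard deviations (SD), and every group had n = 4. Folds printed beside a log2 fold change come from means of log2 values and can differ from ratios of mean counts.

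Gene groups were tested with limma's camera on 48 lists written from general knowledge of the organism, each with at least 5 measured members, at a preset inter-gene correlation of 0.01 and adjusted over the lists of a comparison. The lists covered RNA processing, stress responses, translation, metabolism, the cuticle, the germline, immunity and tissue markers. The same test with a correlation estimated from the data was run beside it. Of 672 list tests, 269 passed with the preset correlation and 21 with the estimated one. Members of a list were counted by the per-gene test over all 12327 genes and again adjusted over the list alone.

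The comparisons, tests, gene lists and the rule for named genes were set before the data were examined. The rule named repo-1 and the 4 mutated genes in every group. For the averaged RNAi effect it took the 12 largest rises and 12 largest falls among called genes of the same sign in all 5 genotypes, for each other contrast of 2 groups the 10 largest each way among called genes whose 4 libraries in one group all lay above those in the other, and for each interaction the 3 largest each way. A mean of at least 100 over all libraries and a locus name were required, so genes known by a sequence name alone were counted and not named. From each list, up to 4 called members with the largest changes could be named. Gene positions came from the Ensembl annotation of WBcel235. A fold against a group without reads was computed against a floor of 3 reads over the group and is a lower bound from counting error alone.

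The share of a mutant's effect kept under RNAi was measured on genes called in batches 1 and 2 of the empty vector groups. The mutant effects on empty vector and on RNAi in batches 3 and 4 were regressed on those in batches 1 and 2, and the ratio of the 2 slopes was taken. The batches were then exchanged and both ratios averaged. Because the labels give the number of a library as its batch, libraries of the same number were checked for pairing. Residual correlations exceeded 0.1 in 11 of 36 pairs of libraries with the same number. Their median was 0.0312 against -0.0137 between different numbers, and every pair exceeded 0.1 in 1 comparison. As set in advance, the model was fitted without a block, and a fit with the replicate block was run as an alternative.

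Alternatives recomputed the results with no filter on low values, a mean of at least 50, pseudocounts of 0.5 and 8, quantile normalization, the replicate block, array quality weights, only the libraries of the groups compared, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, and each library or batch left out. Fits without the 3 libraries with the fewest reads, and measures without the sperm, collagen or molting lists, were chosen after seeing the data. Other splits of the libraries into groups of the same size, 35 for each contrast of 2 groups and 100 draws for the averaged effect and the interactions, were fitted in the same way. The test was also run on simulated data built on the wild type contrast, with 200 genes changed among 11495. It recovered 88.1% of genes changed 1.5-fold and 100% of those changed 2-fold or 4-fold, with 3 false calls. The simulated genes varied independently and without batch structure, and the changed ones had a wild type mean of at least 50. These rates therefore need not hold for comparisons in which most genes were called.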

Results

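Gene expression was measured in whole animals of 5 genotypes on day 1 of adulthood, with and without RNAi against repo-1, which encodes a component of the spliceosome. The series concerns how far long life in mutants depends on splicing factors early in life. eat-2 mutants feed slowly and serve as a model of dietary restriction, and raga-1 encodes a Rag GTPase that activates the target of rapamycin complex. clk-1 encodes a hydroxylase of ubiquinone synthesis, and age-1 encodes the catalytic subunit of the phosphoinositide kinase of the insulin pathway. On empty vector the libraries held 14.8 to 22.4 M reads in wild type, 16.9 to 40.8 M reads in eat-2, 7.69 to 27.6 M reads in raga-1, 13.4 to 21 M reads in clk-1 and 14.8 to 25 M reads in age-1. On repo-1 RNAi they held 18 to 21.3 M reads in wild type, 7.43 to 37 M reads in eat-2, 10.7 to 32 M reads in raga-1, 14.1 to 22.4 M reads in clk-1 and 8.11 to 19 M reads in age-1. Correlations between libraries of a group ranged from 0.952 to 0.992.

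The repo-1 transcript (WBGene00008683, chromosome IV, 12084478 to 12085320, forward strand, WBcel235) was lower under RNAi in all 5 genotypes. In wild type it fell from a mean normalized read count of 839 ± 33.6 (SD, n = 4) to 318.5 ± 16, or 38% of the empty vector level (log2 fold change -1.4 ± 0.087, limma adjusted p = 2.45e-14). It fell to 52.5% in eat-2, 47.7% in raga-1, 40.2% in clk-1 and 45.9% in age-1. On empty vector it stood at 81% of wild type in eat-2, 77.3% in raga-1 and 78.8% in clk-1 (limma adjusted p = 0.0031, 0.000663 and 0.000961), while 95.9% in age-1 did not pass (adjusted p = 0.766). The fall was smaller than in wild type in eat-2, by 0.47 on the log2 scale (adjusted p = 0.00981), and in raga-1, by 0.33 (adjusted p = 0.0246), and the difference did not pass in clk-1 (adjusted p = 0.694) or age-1 (adjusted p = 0.847).

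The mutated genes differed in how far their own transcripts were lowered. raga-1 (WBGene00006414, chromosome II, 11301359 to 11302776) stood at a mean of 38.6 ± 10.5 (SD, n = 4) in its mutant on empty vector against 1514 ± 34.9 in wild type, or 2.55% (limma adjusted p = 6.66e-16). In the raga-1 libraries on RNAi it read 135, 67.9, 12.7 and 27. clk-1 (WBGene00000536, chromosome III, 5277894 to 5279344) stood at 77.5 ± 11.7 against 228 ± 12.9, or 34.1% (adjusted p = 4.22e-12). age-1 (WBGene00000090, chromosome II, 11519328 to 11527054) was at 94.2% of wild type in its mutant (adjusted p = 0.724), but it fell under RNAi to 74.7% in eat-2 (adjusted p = 0.00253), 53.7% in raga-1 (adjusted p = 6.48e-09), 80.2% in clk-1 (adjusted p = 0.016) and 73.9% in age-1 (adjusted p = 0.00405). In wild type its 82.3% did not pass (adjusted p = 0.058). eat-2 (WBGene00001133, chromosome II, 14166878 to 14171658), carried as a point mutation, had group means of 1.55 to 12, below the minimum for testing.

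**Figure D1:**
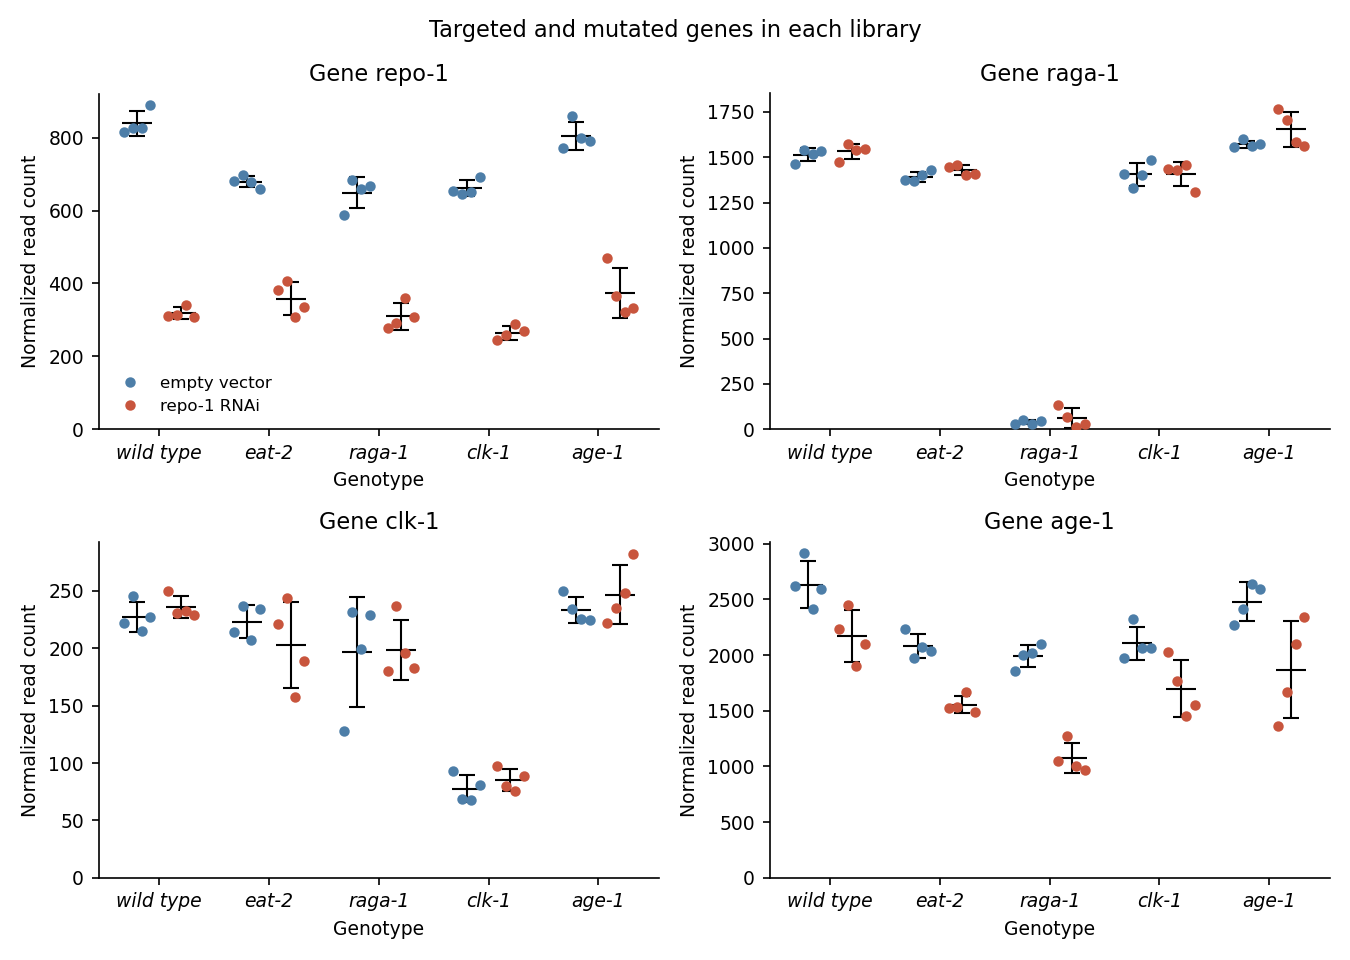
Normalized read counts of repo-1, raga-1, clk-1 and age-1 in each of the 40 libraries, by genotype on the horizontal axis, with empty vector in blue and repo-1 RNAi in red; black bars give the mean and SD of 4 libraries. Mean repo-1 falls from 839 to 318.5 in wild type, and raga-1 stands at 38.6 in its mutant against 1514 in wild type.

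repo-1 RNAi in wild type asked what loss of the splicing factor does in normal animals. Genes of the sperm list, led by the major sperm proteins that move the crawling sperm cell, rose in 38 of 59 measured members and fell in 1 (47 and 1 adjusted over the list alone). Its median log2 fold change was 1.71 (camera adjusted p = 7.16e-15, and adjusted p = 0.563 with an estimated correlation). Examples were msp-33, 4.93-fold higher (2.3 ± 0.457, limma adjusted p = 0.000299), msd-4, 4.29-fold higher (2.1 ± 0.513), and msp-78, 4.24-fold higher (2.08 ± 0.456). Spliceosome genes rose slightly, with 26 of 63 members up and 2 down, repo-1 among the latter (32 and 4 adjusted over the list alone), a median of 0.108 and examples in prp-38 (0.39 ± 0.0593), a tri-snRNP protein, and the splicing regulator rsp-8 (0.34 ± 0.0566) (camera adjusted p = 4.37e-08, and adjusted p = 0.552 with an estimated correlation). Lysosomal genes fell in 20 of 43 members (23 down and 1 up adjusted over the list alone), among them the cathepsin cpr-4, 2.82-fold lower (-1.5 ± 0.134), and vha-6 (-0.54 ± 0.0636), an intestinal proton pump subunit (camera adjusted p = 2.92e-06, and adjusted p = 0.552 with an estimated correlation). Intestine markers fell in 11 of 27 members and rose in 1, with a median of -0.283 and pho-1, an acid phosphatase, at -1.32 ± 0.163 (camera adjusted p = 0.00232, and adjusted p = 0.563 with an estimated correlation; the same counts adjusted over the list alone).

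Among genes with a locus name and a mean of at least 100, the largest rises in wild type under RNAi were in dhs-26, a short-chain dehydrogenase (6.4-fold, 2.68 ± 0.345), acd-1, a sodium channel of the degenerin family (6.2-fold, 2.63 ± 0.304), the glucuronosyltransferase ugt-66 (5.44-fold, 2.45 ± 0.356) and the lectin clec-266 (5.27-fold, 2.40 ± 0.204), with the glutathione transferase gst-24 at 4.19-fold (2.07 ± 0.202). Falls included the lectins clec-222 (13.6-fold, -3.77 ± 0.381) and clec-223 (7.13-fold, -2.83 ± 0.272), the collagen col-135 (5.5-fold, -2.46 ± 0.245) and tbh-1 (4.17-fold, -2.06 ± 0.193), which makes octopamine. limma called 2839 of 12327 genes, 1244 up and 1595 down, and 16 of 48 lists passed. The share of called genes that rose was 43.8% as deposited and 52.3% after quantile normalization. The count was 4460 with array quality weights and 1679 without batch 4.

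repo-1 RNAi in eat-2 raised spliceosome and ribosome biogenesis genes and lowered molting and pharynx genes. Of 63 spliceosome genes 47 rose and 2 fell (49 and 3 adjusted over the list alone). The median was 0.298, with rises in prp-38 (0.73 ± 0.0593), lsm-5 (0.68 ± 0.0801) and the Sm protein snr-6 (0.66 ± 0.066) (camera adjusted p = 1.69e-24, and adjusted p = 0.0399 with an estimated correlation). Ribosome biogenesis genes rose in 20 of 33 members and fell in 1 (21 and 1 adjusted over the list alone). The median was 0.239, with lpd-6 at 0.61 ± 0.0479 (camera adjusted p = 3.99e-10, and adjusted p = 0.0437 with an estimated correlation). Sperm genes rose in 40 of 59 members and fell in 1 (46 and 1 adjusted over the list alone). The median was 1.45 (camera adjusted p = 3.64e-09, and adjusted p = 0.701 with an estimated correlation). Molting genes fell in 22 of 46 members and rose in 2 (the same adjusted over the list alone). The median was -0.541, with wrt-1, a hedgehog-related protein, at -2.97 ± 0.291 (camera adjusted p = 0.0056, and adjusted p = 0.701 with an estimated correlation). Cuticle collagens rose in 33 of 128 members and fell in 14 (the same adjusted over the list alone). The median was 0.304 (camera adjusted p = 0.00727, and adjusted p = 0.884 with an estimated correlation). Pharynx markers fell in 11 of 27 members (11 adjusted over the list alone). The median was -0.272, with phat-5, a mucin-like gland protein, at -4.59 ± 0.526 (camera adjusted p = 0.00621, and adjusted p = 0.701 with an estimated correlation). Genes of the middle and late embryo, 26 of which were measured outside these lists, had a median of -0.443, and 12 of them fell.

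Single genes that rose in eat-2 under RNAi included dhs-26 (13.9-fold, 3.80 ± 0.345), ugt-66 (7.86-fold, 2.97 ± 0.356), gst-24 (5.53-fold, 2.47 ± 0.202) and gpdh-1 (4.83-fold, 2.27 ± 0.195), a glycerol synthesis enzyme of the osmotic response. For the collagens rol-1 and col-49 the fitted rises were 23.9-fold and 14-fold with wide errors (4.58 ± 1.13 and 3.81 ± 0.98). Their mean counts lay much closer, at 415.8 on RNAi against 145.9 on empty vector for rol-1 and 219.4 against 80.26 for col-49. These folds therefore depend on averaging log2 values. Falls included the cuticlins cut-3 (17.7-fold, -4.15 ± 0.549) and cut-2 (8.1-fold, -3.02 ± 0.368), the collagens col-165 (-4.02 ± 0.783) and col-74 (14.7-fold, -3.88 ± 0.866), and the lipocalin-related lpr-5 (4.61-fold, -2.2 ± 0.346). limma called 4628 genes, 1996 up and 2632 down, and 13 of 48 lists passed. The share of called genes that rose was 43.1% as deposited and 53.5% after quantile normalization.

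repo-1 RNAi in raga-1 gave the largest response, in which oocyte genes fell and genes of several body tissues rose. Here and in the raga-1 interaction the median of all tested genes was not at 0: it was 0.101 as deposited (-0.0664 after quantile normalization) and 0.121 in the interaction (-0.0463), and changes are to be read relative to it. Oocyte and germline genes fell in 53 of 58 members and rose in 1 (the same adjusted over the list alone). The median was -0.636, with falls in the yolk receptor rme-2 (-1.22 ± 0.0538) and the germ granule helicase glh-2 (-1.17 ± 0.0553) (camera adjusted p = 4.68e-21, and adjusted p = 0.0959 with an estimated correlation). All 38 cell cycle and DNA replication genes fell (38 adjusted over the list alone). The median was -0.601, with mcm-4, a helicase subunit of replication, at -1.13 ± 0.117 (camera adjusted p = 3.41e-19, and adjusted p = 0.0302 with an estimated correlation). All 33 proteasome genes fell (33 adjusted over the list alone). The median was -0.572, with rpt-4 at -0.83 ± 0.0414 (camera adjusted p = 5.42e-16, and adjusted p = 0.054 with an estimated correlation). Neuron markers rose in 58 of 66 members and fell in 1 (59 and 1 adjusted over the list alone). The median was 0.757 (0.465 after quantile normalization), with the neuropeptide gene flp-28 at 1.18 ± 0.104 (camera adjusted p = 1.73e-09, and adjusted p = 0.0029 with an estimated correlation). Body wall muscle markers rose in 32 of 33 members and fell in 1 (32 and 1 adjusted over the list alone). The median was 0.817, with troponin tni-1 at 1.07 ± 0.126 (camera adjusted p = 1.03e-13, and adjusted p = 0.138 with an estimated correlation). Sperm genes rose in 56 of 59 members and fell in 1 (the same adjusted over the list alone). The median was 3.05 (camera adjusted p = 1.46e-11, and adjusted p = 0.27 with an estimated correlation).

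Collagens rose with the tissue markers in raga-1 under RNAi, in 107 of 128 members against 3 that fell (109 and 3 adjusted over the list alone). The median was 1.73, with col-58 at 3.05 ± 0.61 (camera adjusted p = 1.21e-09, and adjusted p = 0.267 with an estimated correlation). The 12 measured genes of the mitochondrial genome all rose (12 adjusted over the list alone). The median was 0.71, with ctc-3, a cytochrome oxidase subunit, at 1.02 ± 0.0838 (camera adjusted p = 0.000228, and adjusted p = 0.213 with an estimated correlation). Nuclear genes of the mitochondrial ribosome fell in 58 of 71 members (58 adjusted over the list alone). The median was -0.35, with mrpl-23 at -0.96 ± 0.116 (camera adjusted p = 4.58e-10, and adjusted p = 0.0302 with an estimated correlation). Spliceosome genes fell in 34 of 63 members and rose in 6 (the same adjusted over the list alone). The median was -0.149 (camera adjusted p = 0.00315, and adjusted p = 0.414 with an estimated correlation). After quantile normalization the spliceosome median was -0.0341 and the list did not pass (camera adjusted p = 0.928). Single rises included msp-79 (25.4-fold, 4.67 ± 0.808) and msp-56 (21.9-fold, 4.45 ± 0.744), and falls included clec-222 (13.2-fold, -3.73 ± 0.381), tbh-1 (7.29-fold, -2.87 ± 0.193), the peroxidase skpo-1 (4.51-fold, -2.17 ± 0.195) and acdh-1 (4.79-fold, -2.26 ± 0.19), an acyl-CoA dehydrogenase of the propionate shunt. limma called 8766 genes, 4703 up and 4063 down, and 27 of 48 lists passed. The share of called genes that rose was 53.7% as deposited and 43.2% after quantile normalization.

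repo-1 RNAi in clk-1 raised sperm, ribosomal and respiratory genes. Sperm genes rose in 55 of 59 members and fell in 2 (the same adjusted over the list alone). The median was 4.03, with msp-79 at 54.9-fold (5.78 ± 0.808, limma adjusted p = 3.39e-07) (camera adjusted p = 2.43e-25, and adjusted p = 0.407 with an estimated correlation). Cytosolic ribosomal proteins rose in 67 of 79 members and fell in 3 (69 and 3 adjusted over the list alone). The median was 0.334 (0.173 after quantile normalization), with rpl-30 at 0.61 ± 0.0674 (camera adjusted p = 9.75e-17, and adjusted p = 0.453 with an estimated correlation). Nuclear genes of oxidative phosphorylation rose in 37 of 49 members and fell in 3 (38 and 3 adjusted over the list alone). The median was 0.259, with gas-1, a complex I subunit, at 0.72 ± 0.0816 (camera adjusted p = 2.57e-09, and adjusted p = 0.407 with an estimated correlation). The mitochondrial genome rose in 11 of 12 members (12 adjusted over the list alone). The median was 0.617 (camera adjusted p = 1.2e-05, and adjusted p = 0.407 with an estimated correlation). Molting genes fell in 19 of 46 members and rose in 6 (the same adjusted over the list alone). The median was -0.73, with mlt-11, a protease inhibitor of the molt, at -2.4 ± 0.286 (camera adjusted p = 0.0081, and adjusted p = 0.522 with an estimated correlation). Cuticle collagens rose in 43 of 128 members and fell in 16 (the same adjusted over the list alone). The median was 0.707 (camera adjusted p = 0.000911, and adjusted p = 0.601 with an estimated correlation). Early zygotic genes fell in 18 of 33 members and rose in 3 (the same adjusted over the list alone). The median was -0.501, with end-1, an endoderm regulator, at -2.41 ± 0.494 (camera adjusted p = 0.000392, and adjusted p = 0.407 with an estimated correlation). Of the 26 genes of the middle and late embryo 16 fell, with a median of -0.751.

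Single genes that fell in clk-1 under RNAi included clec-222 (141-fold, -7.14 ± 0.381), col-165 (76.7-fold, -6.26 ± 0.783), col-74 (68.3-fold, -6.09 ± 0.866), cut-3 (67.9-fold, -6.08 ± 0.549), clec-223 (16-fold, -4.0 ± 0.272), tbh-1 (13.6-fold, -3.77 ± 0.193) and the collagen dpy-17 (12.2-fold, -3.6 ± 0.312). limma called 5708 genes, 2934 up and 2774 down, and 20 of 48 lists passed. The 4 RNAi libraries stood apart by batch in their sperm reads, at 0.0237% (95% Wilson interval 0.0229 to 0.0245%) and 0.03% (0.0292 to 0.0308%) in batches 2 and 1 against 0.112% (0.11 to 0.114%) and 0.128% (0.127 to 0.13%) in batches 4 and 3. All of these lay above the 0.00659 to 0.00795% of the clk-1 libraries on empty vector, and such intervals cover counting error alone. The same libraries parted on the first principal component of all tested genes, at 12.2 and 15.4 in batches 2 and 1 against 52.7 and 57.9 in batches 4 and 3. Sperm reads were lower in batches 1 and 2 than in batches 3 and 4 in other groups too. One was eat-2 on empty vector, at 0.00812% and 0.0103% against 0.0232% and 0.0224%. It also held for eat-2 on RNAi, raga-1 on empty vector and age-1 on RNAi, but not for the remaining groups. Within batches 1 and 2, and within batches 3 and 4, the RNAi medians in clk-1 were 2.79 and 5.14 for the sperm list, 0.362 and 0.308 for the ribosomal list, and 0.276 and 0.273 for oxidative phosphorylation. They were 0.425 and 0.741 for the mitochondrial genome, -0.691 and -0.206 for the molting list, 0.208 and 1.01 for the collagens and -0.48 and -0.552 for the early zygotic list.

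repo-1 RNAi in age-1 raised sperm and spliceosome genes and lowered lysosomal genes. Sperm genes rose in 40 of 59 members and fell in 1 (47 and 1 adjusted over the list alone). The median was 1.7, with msp-51 at 4.54-fold (2.18 ± 0.417) (camera adjusted p = 4.75e-14, and adjusted p = 0.712 with an estimated correlation). Spliceosome genes rose in 32 of 63 members and fell in 1 (36 and 1 adjusted over the list alone). The median was 0.132, with prp-38 at 0.41 ± 0.0593 (camera adjusted p = 1.75e-07, and adjusted p = 0.701 with an estimated correlation). Lysosomal genes fell in 11 of 43 members and rose in 2 (12 and 2 adjusted over the list alone), with cpr-4 at -1.1 ± 0.134 (camera adjusted p = 0.00259, and adjusted p = 0.701 with an estimated correlation). Single rises included clec-41 (3.95-fold, 1.98 ± 0.171) and gst-24 (3.8-fold, 1.93 ± 0.202), and falls included clec-222 (8.2-fold, -3.04 ± 0.381), clec-223 (4.13-fold, -2.05 ± 0.272), col-135 (3.61-fold, -1.85 ± 0.245), tbh-1 (3.06-fold, -1.61 ± 0.193) and acs-2 (2.51-fold, -1.33 ± 0.397), an acyl-CoA synthetase. limma called 2572 genes, 1310 up and 1262 down, and 12 of 48 lists passed. The count was 1067 in a fit to these 8 libraries alone, 1316 without batch 3 and 1433 without batch 2.

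Averaged over the 5 genotypes, repo-1 RNAi raised sperm genes most. The sperm list rose in 57 of 59 members and fell in 1 (the same adjusted over the list alone). The median was 2.42 (camera adjusted p = 4.61e-21, and adjusted p = 0.441 with an estimated correlation). Among genes of the same sign in all 5 genotypes with a locus name and a mean of at least 100, the 12 largest rises were all in msp, msd and nspd genes, from msp-79 (8.61-fold, 3.11 ± 0.361) and msp-19 (7.08-fold, 2.82 ± 0.217) down to msp-40 (6.16-fold, 2.62 ± 0.228). Falls included clec-222 (17.6-fold, -4.14 ± 0.17), clec-223 (5.58-fold, -2.48 ± 0.121), tbh-1 (5.42-fold, -2.44 ± 0.0863), the transthyretin-related ttr-42 (5.06-fold, -2.34 ± 0.119), col-135 (3.59-fold, -1.85 ± 0.11), skpo-1 (3.55-fold, -1.83 ± 0.0873) and clec-150 (3.22-fold, -1.69 ± 0.0256). inx-8, an innexin of the gonadal sheath, was 2.3-fold lower (-1.2 ± 0.0697). Neuron markers rose in 42 of 66 members and fell in 1 (the same adjusted over the list alone). The median was 0.217, with flp-28 at 0.67 ± 0.0463 (camera adjusted p = 4.52e-06, and adjusted p = 0.043 with an estimated correlation). Proteasome genes fell in 28 of 33 members (28 adjusted over the list alone). The median was -0.177, with rpt-4 at -0.38 ± 0.0185 (camera adjusted p = 2.9e-09, and adjusted p = 0.441 with an estimated correlation). Both averages lean on raga-1, where the list medians of the RNAi libraries had means of 0.746 for neuron markers and -0.544 for the proteasome. In clk-1 the neuron medians were 0.292 in batches 1 and 2 and 0.401 in batches 3 and 4. The proteasome medians there were -0.0645 and -0.135. limma called 8092 genes, 3871 up and 4221 down, and 18 of 48 lists passed.

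**Figure D2:**
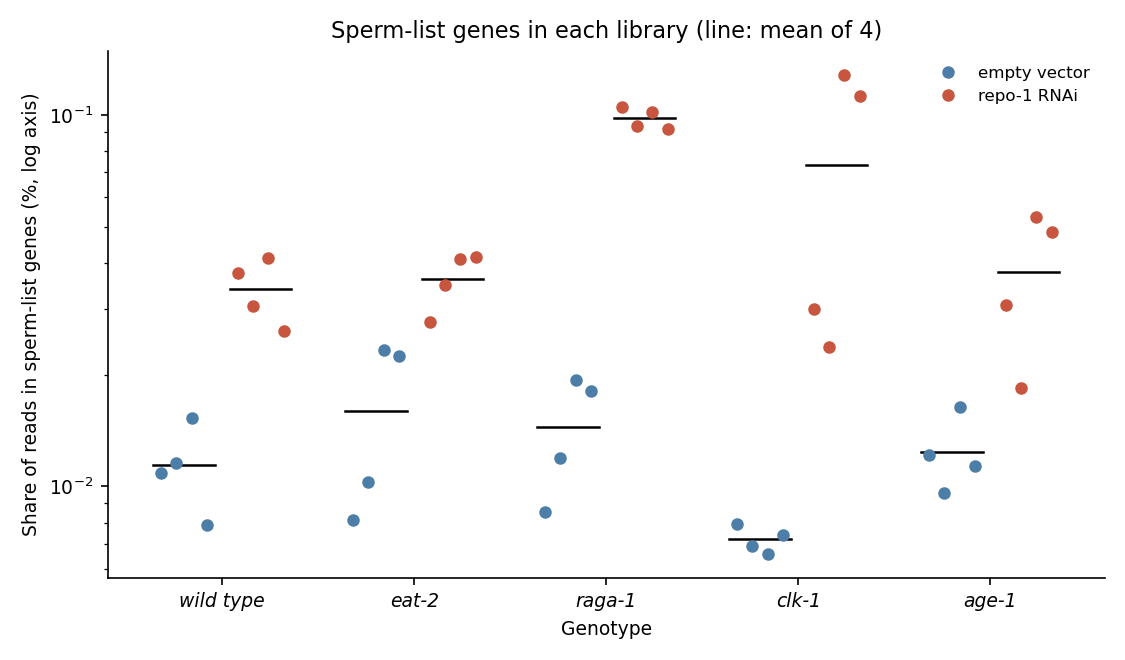
Percent of all reads in genes of the sperm list (log axis) in each of the 40 libraries by genotype, with empty vector in blue, repo-1 RNAi in red and a line at the mean of 4 libraries. The mean rises from 0.0114% to 0.0339% in wild type, from 0.0145% to 0.098% in raga-1 and from 0.00721% to 0.0735% in clk-1, where the 4 RNAi libraries run from 0.0237% to 0.128%.

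Sperm reads rose under RNAi in each genotype as a share of the library. The mean share went from 0.0114 ± 0.00302% (SD, n = 4) to 0.0339 ± 0.00679% in wild type, from 0.016 ± 0.00792% to 0.0362 ± 0.00641% in eat-2, from 0.0145 ± 0.00511% to 0.098 ± 0.00643% in raga-1, from 0.00721 ± 0.000597% to 0.0735 ± 0.0544% in clk-1 and from 0.0124 ± 0.00287% to 0.0377 ± 0.016% in age-1. In every genotype the lowest RNAi library lay above the highest empty vector library. The responses of different genotypes were correlated across genes, which are not independent replicates. Over the 10 pairs of genotypes Pearson's r had a median of 0.495, from 0.293 between eat-2 and raga-1 (Spearman's rho 0.192) to 0.739 between eat-2 and clk-1 (rho 0.622), with 0.704 between wild type and age-1 (rho 0.675). In all 5 genotypes 265 genes rose and 343 fell, against 1.94 and 2.59 for independent lists, and 31 of the 265 were on the sperm list.

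On empty vector, eat-2 against wild type showed higher molting, pharynx and neuron genes and lower germline, yolk and aminoacyl-tRNA synthetase genes. Molting genes rose in 30 of 46 members and fell in 7 (31 and 7 adjusted over the list alone). The median was 2.22, with lpr-3, a lipocalin of the apical matrix, at 3.75 ± 0.345 (camera adjusted p = 3.59e-06, and adjusted p = 0.155 with an estimated correlation). The 26 measured genes of the middle and late embryo moved the same way, with 23 rising and a median of 1.56. Pharynx markers rose in 19 of 27 members (20 adjusted over the list alone). The median was 1.22 (0.728 after quantile normalization), with phat-5 at 6.05 ± 0.526 (camera adjusted p = 5.25e-07, and adjusted p = 0.101 with an estimated correlation). Neuron markers rose in 43 of 66 members and fell in 2 (44 and 2 adjusted over the list alone). The median was 0.486 (0.0944 after quantile normalization), with aex-3 at 1.2 ± 0.11 (camera adjusted p = 2.58e-07, and adjusted p = 0.0139 with an estimated correlation). Aminoacyl-tRNA synthetases, which load amino acids onto tRNAs, fell in 30 of 32 members (31 adjusted over the list alone). The median was -0.269, with gars-1 at -0.5 ± 0.0441 (camera adjusted p = 1.83e-09, and adjusted p = 0.0374 with an estimated correlation). Oocyte and germline genes fell in 53 of 58 members and rose in 1 (the same adjusted over the list alone). The median was -0.253 (-0.12 after quantile normalization, where the median of all genes was -0.098), with fbf-2 at -0.65 ± 0.069 (camera adjusted p = 1.67e-12, and adjusted p = 0.159 with an estimated correlation). All 6 vitellogenins, the yolk proteins, were lower, with a median of -0.817 (-0.772 with edgeR's scaling) (camera adjusted p = 0.00021, and adjusted p = 0.173 with an estimated correlation; 6 adjusted over the list alone). Their share of reads was 10.2 ± 0.42% (SD, n = 4) in eat-2 and 15.2 ± 0.435% in wild type.

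Single genes higher in eat-2 than in wild type included mct-2, a monocarboxylate transporter gene with no reads in wild type and a mean of 297 ± 271 (SD, n = 4) in eat-2. Against counting error alone that mean of mct-2 was at least 391-fold higher. They also included cut-3 (29-fold, 4.86 ± 0.549), col-165 (28.4-fold, 4.83 ± 0.783), cut-2 (21.1-fold, 4.4 ± 0.368), the collagens dpy-14 (17.5-fold, 4.13 ± 0.349) and dpy-17 (16.6-fold, 4.05 ± 0.312) and hch-1, an astacin protease of hatching (16.3-fold, 4.03 ± 0.438). Lower genes included col-135 (9.23-fold, -3.21 ± 0.245), ugt-63 (7.89-fold, -2.98 ± 0.18), the sphingomyelinase asm-3 (6.44-fold, -2.69 ± 0.362) and agl-1, a glycogen debranching enzyme (3.02-fold, -1.59 ± 0.0559). limma called 7030 genes, 3356 up and 3674 down, and 28 of 48 lists passed. The share of called genes that were higher was 47.7% as deposited and 37.8% after quantile normalization.

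On empty vector, raga-1 against wild type showed higher neuron genes and lower ribosomal, aminoacyl-tRNA synthetase and early zygotic genes. Neuron markers rose in 40 of 66 members and fell in 2 (43 and 3 adjusted over the list alone). The median was 0.494, with flp-8 at 1.06 ± 0.135 (camera adjusted p = 7.06e-09, and adjusted p = 0.00352 with an estimated correlation). Aminoacyl-tRNA synthetases fell in 26 of 32 members (26 adjusted over the list alone). The median was -0.275, with gars-1 at -0.58 ± 0.0441 (camera adjusted p = 3.89e-10, and adjusted p = 0.0234 with an estimated correlation). Cytosolic ribosomal proteins fell in 66 of 79 members and rose in 2 (69 and 2 adjusted over the list alone). The median was -0.208, with rps-20 at -0.38 ± 0.0381 (camera adjusted p = 6.7e-09, and adjusted p = 0.53 with an estimated correlation). Genes induced by DAF-16, the transcription factor held back by insulin signalling, rose in 12 of 18 members and fell in 1 (the same adjusted over the list alone). The median was 0.458, with the ferritin ftn-1 at 3.24 ± 0.399 (camera adjusted p = 2.63e-05, and adjusted p = 0.111 with an estimated correlation). Genes repressed by DAF-16 also rose, in 13 of 21 members against 3 that fell (13 and 4 adjusted over the list alone). The median was 0.827, with dod-22 at 2.28 ± 0.267 (camera adjusted p = 0.000955, and adjusted p = 0.0974 with an estimated correlation). Early zygotic genes fell in 16 of 33 members and rose in 1 (the same adjusted over the list alone). The median was -0.693, with sdz-28 at -1.46 ± 0.193 (camera adjusted p = 0.00201, and adjusted p = 0.225 with an estimated correlation). The vitellogenins took 22.1 ± 1.17% of reads (SD, n = 4) against 15.2 ± 0.435% in wild type, and their list did not pass.

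Among single genes, raga-1 animals on empty vector had higher catp-3, a cation-transporting ATPase (23.1-fold, 4.53 ± 0.215), gpdh-1 (14.6-fold, 3.87 ± 0.195) and hmit-1.1, an inositol transporter (13.7-fold, 3.77 ± 0.206). The asparagine synthetase asns-2 was 13.5-fold higher (3.75 ± 0.193) and the acyltransferase dgat-2 9.38-fold higher (3.23 ± 0.231). Lower genes besides raga-1 itself included the lipase lipl-1 (7.46-fold, -2.90 ± 0.306), acdh-1 (5.13-fold, -2.36 ± 0.19) and the endoribonuclease endu-2 (4.92-fold, -2.3 ± 0.214). limma called 5684 genes, 2431 up and 3253 down, and 22 of 48 lists passed.

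On empty vector, clk-1 against wild type showed lower ribosomal, proteasome and sperm genes and higher DAF-16 induced, hypoxia and mitochondrial stress genes. Cytosolic ribosomal proteins fell in 78 of 79 members (78 adjusted over the list alone). The median was -0.628 (-0.389 after quantile normalization), with rpl-1 at -0.84 ± 0.0605 (camera adjusted p = 9.87e-30, and adjusted p = 0.174 with an estimated correlation). Proteasome genes fell in 32 of 33 members (32 adjusted over the list alone). The median was -0.467, with rpn-12 at -0.64 ± 0.0409 (camera adjusted p = 3.7e-16, and adjusted p = 0.0483 with an estimated correlation). DAF-16 induced genes rose in 14 of 18 members and fell in 2 (the same adjusted over the list alone). The median was 1.17, with rises in the superoxide dismutase sod-3 (2.15 ± 0.171) and icl-1 of the glyoxylate cycle (2.22 ± 0.166) (camera adjusted p = 1.43e-06, and adjusted p = 0.0483 with an estimated correlation). The mitochondrial unfolded protein response list rose in 12 of 18 members and fell in 4 (the same adjusted over the list alone). The median was 0.39 (camera adjusted p = 0.000991, and adjusted p = 0.0227 with an estimated correlation). Members that changed included the cytochrome P450 genes cyp-14A4 (5.45 ± 0.375), cyp-14A1 (2.82 ± 0.255) and cyp-14A3 (-2.53 ± 0.663). Other cytochrome P450 genes, such as cyp-13A7 and cyp-13A5, rose in clk-1 as well. These members alone therefore do not mark mitochondrial stress. Hypoxia genes rose in 8 of 14 members (8 adjusted over the list alone). The median was 0.387, with lactate dehydrogenase ldh-1 at 1.91 ± 0.0586 (camera adjusted p = 0.000433, and adjusted p = 0.0564 with an estimated correlation). Sperm genes fell in 41 of 59 members and rose in 2 (43 and 3 adjusted over the list alone). The median was -1.54 (camera adjusted p = 0.000812, and adjusted p = 0.651 with an estimated correlation). Molting genes rose in 28 of 46 members and fell in 10 (the same adjusted over the list alone). The median was 1.26 (camera adjusted p = 0.0107, and adjusted p = 0.549 with an estimated correlation), and 21 of 26 genes of the middle and late embryo rose, with a median of 1.2.

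Single rises in clk-1 on empty vector included detoxification genes, with cyp-13A7 (192-fold, 7.58 ± 0.489), cyp-13A5 (63.5-fold, 5.99 ± 0.2) and cyp-33C8 (28.3-fold, 4.82 ± 0.163), followed by acs-2 (25.5-fold, 4.67 ± 0.397) and the cadmium-responsive cdr-2 (20.2-fold, 4.34 ± 0.157). Falls included the fatty acid desaturase fat-7 (37.4-fold, -5.22 ± 0.431), pud-3 (32.4-fold, -5.02 ± 0.262), asm-3 (18.3-fold, -4.19 ± 0.362) and the vitellogenins vit-3 (10.7-fold, -3.42 ± 0.137) and vit-1 (9.97-fold, -3.32 ± 0.136). All vitellogenins together took 13.4 ± 0.5% of reads (SD, n = 4) in clk-1 and 15.2 ± 0.435% in wild type. limma called 7181 genes, 3432 up and 3749 down, and 22 of 48 lists passed.

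On empty vector, age-1 against wild type showed the DAF-16 target genes as its clearest group. Of 18 DAF-16 induced genes 17 rose (18 adjusted over the list alone). The median was 0.796, with rises in ftn-1 (11.5-fold, 3.52 ± 0.399), dod-3 (7.74-fold, 2.95 ± 0.298) and the metallothionein mtl-1 (2.83 ± 0.342) (camera adjusted p = 1.25e-38, and adjusted p = 8e-07 with an estimated correlation). DAF-16 repressed genes fell in 7 of 21 members and rose in 3 (8 and 3 adjusted over the list alone). The median was -0.268, with dod-24 at -2.14 ± 0.324 (camera adjusted p = 0.0022, and adjusted p = 0.0736 with an estimated correlation). Glycolysis and gluconeogenesis genes rose in 12 of 22 members (16 adjusted over the list alone). The median was 0.174, with pck-2 at 0.46 ± 0.0371 (camera adjusted p = 8.47e-14, and adjusted p = 0.0728 with an estimated correlation). Other single rises included lea-1, a desiccation protein (4.39-fold, 2.13 ± 0.0744), nnt-1, a mitochondrial transhydrogenase (5.4-fold, 2.43 ± 0.178), and spp-2, a saposin-like peptide (3.09-fold, 1.63 ± 0.142). Falls included maph-1.2 (4.42-fold, -2.14 ± 0.0678) and ugt-64 (3.01-fold, -1.59 ± 0.143). limma called 1045 genes, 587 up and 458 down, and 14 of 48 lists passed. The count was 1638 with array quality weights, 653 without age-1 empty vector replicate 1, and 590, 595 and 561 without batches 1, 2 and 4.

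The mutants' effects on empty vector share their wild type libraries, which alone gave a correlation of 0.501 and a covariance of 0.0353 across simulated unchanged genes. Between eat-2 and clk-1 Pearson's r was 0.621 with a covariance of 0.442, and 0.563 with the wild type libraries split between the mutants. These mutants shared 2165 higher and 2473 lower genes, against 934.4 and 1117 for independent lists. Between eat-2 and raga-1 the covariance was 0.109 and the split r 0.157, with 1311 and 2222 shared genes against 661.8 and 969.5. For both pairs of mutants, the counts for independent lists take no account of the shared wild type libraries and may be too low. The other covariances were 0.0797 for raga-1 and clk-1, 0.0716 for raga-1 and age-1, 0.0623 for clk-1 and age-1, and 0.0333 for eat-2 and age-1, which did not exceed the simulated value.

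The interactions asked whether a mutant responded to repo-1 RNAi as wild type did. Each subtracts the mutant's difference from wild type on empty vector, so a move back toward the wild type level also appears in it. In eat-2 on empty vector, molting genes, cut-3, col-165 and col-74 were already higher than in wild type, and col-135 was lower. In eat-2, spliceosome genes rose more than in wild type in 28 of 63 members (36 adjusted over the list alone). The median difference was 0.192, with snr-4 at 0.42 ± 0.0629 (camera adjusted p = 4.29e-15, and adjusted p = 0.0797 with an estimated correlation). Detoxification genes of the SKN-1 pathway were higher in 5 of 22 members (7 adjusted over the list alone). The median was 0.236, with the regulator skn-1 itself at 0.27 ± 0.059 (camera adjusted p = 0.000567, and adjusted p = 0.0362 with an estimated correlation). Molting genes were lower in 15 of 46 members and higher in 2 (20 and 2 adjusted over the list alone). The median was -0.948, with wrt-1 at -3.05 ± 0.411 (camera adjusted p = 1.45e-07, and adjusted p = 0.198 with an estimated correlation). The mitochondrial genome was higher in 9 of 12 members (11 adjusted over the list alone). The median was 0.524, with ctc-3 at 0.63 ± 0.119 (camera adjusted p = 1.98e-08, and adjusted p = 0.136 with an estimated correlation). Among called genes with a locus name and a mean of at least 100, the 3 largest differences each way were in cut-3 (-5.04 ± 0.777), col-165 (-4.14 ± 1.11), col-74 (-4.07 ± 1.22), col-135 (1.75 ± 0.347), gpdh-1 (1.41 ± 0.276) and ugt-26 (1.08 ± 0.266). limma called 1320 genes, 490 up and 830 down, and 16 of 48 lists passed. The count was 2219 in a fit to the 16 libraries alone, 2639 with array quality weights, and 708, 773 and 696 without batches 2, 3 and 4.

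In raga-1 the interaction had oocyte and replication genes lower and sperm, neuron and lysosomal genes higher than the wild type response did. Cell cycle and DNA replication genes were lower in 37 of 38 members (37 adjusted over the list alone). The median difference was -0.626, with mcm-5 at -0.93 ± 0.0772 (camera adjusted p = 9.94e-24, and adjusted p = 0.0182 with an estimated correlation). Neuron markers were higher in 51 of 66 members and lower in 1 (the same adjusted over the list alone). The median was 0.704 (0.42 after quantile normalization), with the neuropeptide gene pdf-1 at 1.2 ± 0.254 (camera adjusted p = 1.56e-08, and adjusted p = 0.00511 with an estimated correlation). Oocyte genes were lower in 50 of 58 members and higher in 1 (the same adjusted over the list alone). The median was -0.566, with the oocyte regulator oma-1 at -0.88 ± 0.0731 (camera adjusted p = 8.87e-23, and adjusted p = 0.0545 with an estimated correlation). Sperm genes were higher in 24 of 59 members (14 adjusted over the list alone). The median was 1.4 (camera adjusted p = 0.000321, and adjusted p = 0.552 with an estimated correlation). Spliceosome genes were lower in 44 of 63 members and higher in 3 (45 and 3 adjusted over the list alone). The median was -0.251, with rsp-6 at -0.62 ± 0.0969 (camera adjusted p = 5.9e-08, and adjusted p = 0.17 with an estimated correlation). Lysosomal genes were higher in 32 of 43 members and lower in 2 (the same adjusted over the list alone). The median was 0.437, with cpr-4 at 1.97 ± 0.19 (camera adjusted p = 1.56e-08, and adjusted p = 0.051 with an estimated correlation). Among called genes with a locus name and a mean of at least 100, the 3 largest each way were in msp-79 (2.94 ± 1.14), msp-56 (2.62 ± 1.05), acs-2 (2.11 ± 0.562), pigb-1 (-2.21 ± 0.217), his-48 (-1.81 ± 0.334) and acdh-1 (-1.75 ± 0.269). limma called 6852 genes, 3499 up and 3353 down, and 30 of 48 lists passed. The share of called genes that were higher was 51.1% as deposited and 38.8% after quantile normalization.

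In clk-1 the interaction was led by ribosomal, mitochondrial and sperm genes on the higher side and molting genes on the lower side. On empty vector, ribosomal genes were already lower in clk-1 than in wild type and molting genes higher. Their differences therefore include a move back toward the wild type level. Cytosolic ribosomal proteins were higher in 74 of 79 members (75 adjusted over the list alone). The median difference was 0.432 (0.179 after quantile normalization), with rla-2 at 0.54 ± 0.0901 (camera adjusted p = 2.33e-30, and adjusted p = 0.266 with an estimated correlation). Lysosomal genes were higher in 26 of 43 members (29 up and 1 down adjusted over the list alone). The median was 0.374, with the nuclease nuc-1 at 0.75 ± 0.0973 (camera adjusted p = 6.37e-13, and adjusted p = 0.0581 with an estimated correlation). Sperm genes were higher in 44 of 59 members (49 adjusted over the list alone). The median was 2.27, with msp-79 at 4.05 ± 1.14, nspd-2 at 3.18 ± 0.611 and msp-81 at 2.97 ± 0.625 (camera adjusted p = 5e-12, and adjusted p = 0.368 with an estimated correlation). This difference includes a lower start, as sperm reads on empty vector were 0.00721% in clk-1 and 0.0114% in wild type. On RNAi, clk-1 lay below wild type in batches 1 and 2 (0.02995% and 0.02369% against 0.03745% and 0.03056%). It lay above wild type in batches 3 and 4 (0.1282% and 0.1122% against 0.04129% and 0.02617%). The mitochondrial genome was higher in 11 of 12 members (12 adjusted over the list alone). The median was 0.792 (camera adjusted p = 1.75e-08, and adjusted p = 0.228 with an estimated correlation). Molting genes were lower in 17 of 46 members and higher in 5 (18 and 6 adjusted over the list alone). The median was -0.916 (camera adjusted p = 0.000144, and adjusted p = 0.293 with an estimated correlation), and single differences included cut-3 (-6.98 ± 0.777), col-165 (-6.39 ± 1.11) and col-74 (-6.28 ± 1.22). Cuticle collagens as a list were higher in 32 of 128 members and lower in 15 (the same adjusted over the list alone). The median was 0.524 (0.309 after quantile normalization) and the mean 0.00828 (camera adjusted p = 0.0181, and adjusted p = 0.713 with an estimated correlation). Within batches 1 and 2, and within batches 3 and 4, the median differences were 0.465 and 0.396 for the ribosomal list, 0.342 and 0.42 for the lysosomal list and 1.13 and 3.42 for the sperm list. They were 0.695 and 0.869 for the mitochondrial genome, -1.15 and -0.628 for the molting list and -0.0192 and 0.813 for the collagens. limma called 2908 genes, 1688 up and 1220 down, and 23 of 48 lists passed. The share of called genes that were higher was 58% as deposited and 50.6% after quantile normalization. The count was 4622 with array quality weights, and 1678 and 1908 without batches 3 and 4.

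In age-1 limma called 1 gene in the interaction, drd-50 (WBGene00018643), which was chosen after its values were seen because its mean lies below the minimum for named genes. Its mean went from 6.55 ± 3.04 (SD, n = 4) to 42.5 ± 13.3 in age-1 and from 43.2 ± 11.8 to 51.8 ± 5.01 in wild type, a difference of 2.31 ± 0.375 on the log2 scale (limma adjusted p = 0.00549). Cytosolic ribosomal proteins were slightly higher as a list, with a median of 0.122 (0.0348 after quantile normalization) and no member past the test in either count (camera adjusted p = 5.06e-12, and adjusted p = 0.836 with an estimated correlation). Lysosomal genes were too, with a median of 0.0823 (0.0134 after quantile normalization, where the list did not pass) and no member past the test in either count (camera adjusted p = 0.0246, and adjusted p = 0.836 with an estimated correlation). In total, 8 of 48 lists passed. Before adjustment 695 genes had p under 0.05, edgeR called 1 gene and DESeq2 called 8. The count was 0 in a fit to the 16 libraries alone, 56 with array quality weights, 2 without wild type repo-1 RNAi replicate 1, 3 without age-1 empty vector replicate 3, and 4 and 0 without batches 3 and 4.

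Whether a mutant's effect on expression remained under RNAi was measured on genes chosen in other libraries. In eat-2, 48.6% and 53.1% of the effect was kept in the 2 exchanges of batches (mean 50.8%), and in clk-1 48.4% and 60.4% (mean 54.4%). In raga-1 the effect measured 115% and 170% of its size on empty vector (mean 142%). The slopes on RNAi were alike, at 0.958 and 0.959, while those on empty vector were 0.835 and 0.566. The slope of 0.566 was measured in batches 1 and 2, which hold raga-1 empty vector replicate 1 (7.69 M reads, array quality weight 0.167). The gap between 115% and 170% thus lay in the empty vector slope, and an enlarged effect under RNAi is not shown. With no filter on low values the exchange at 115% gave a fraction of 0.757, which is below its size on empty vector. In age-1 the values were 96.6% on 757 genes and 136% on 146 genes (mean 116%), and this value turned negative with other choices of genes. The slopes weight genes by the size of their effect on empty vector, so the share kept leans on the genes that changed most. In eat-2 the largest rises among genes with a locus name included the cuticle genes cut-3 and col-165, which fell there under RNAi. The share kept therefore need not describe most genes of a mutant's effect.

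**Figure D3:**
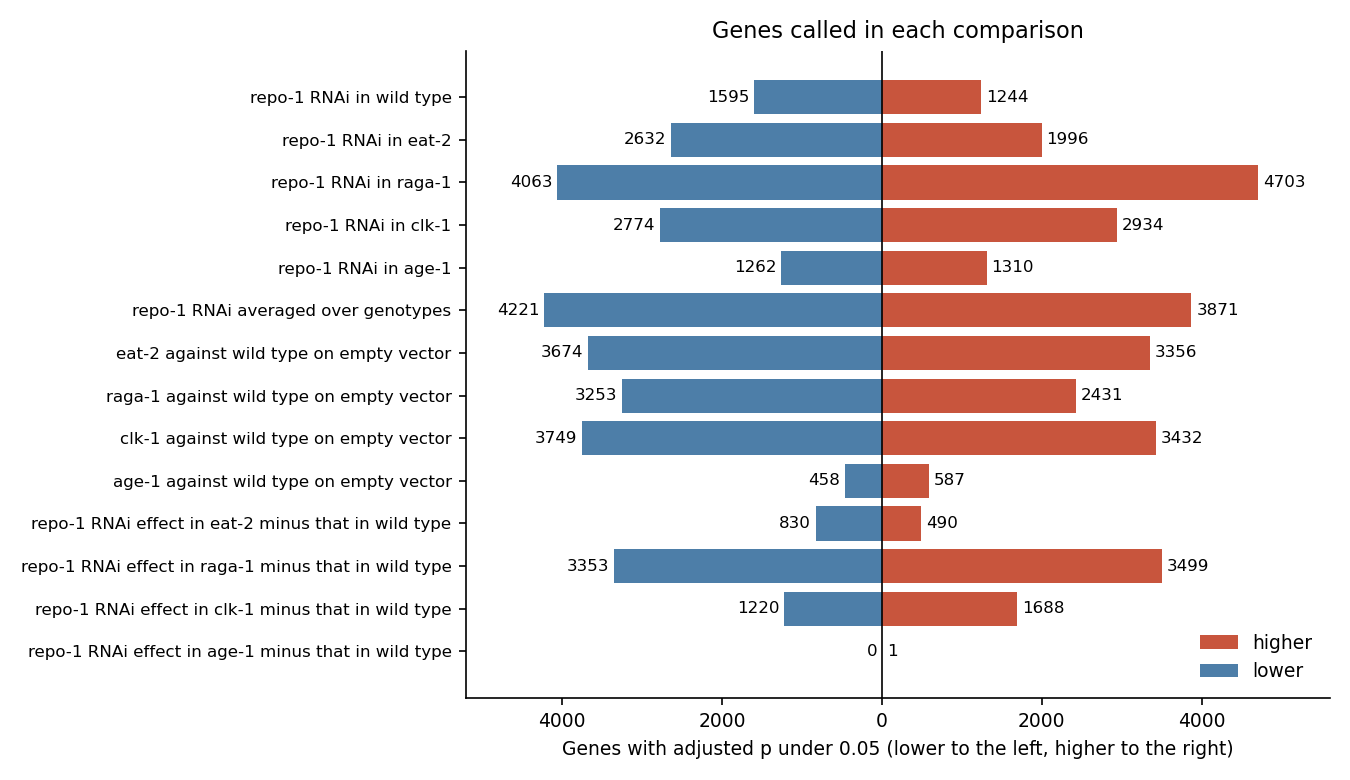
Number of genes called by limma (adjusted p under 0.05) in each of the 14 comparisons, with genes higher to the right in red and genes lower to the left in blue. Counts run from 4703 up and 4063 down for repo-1 RNAi in raga-1 to 1 up and 0 down for the age-1 interaction.

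**Figure D4:**
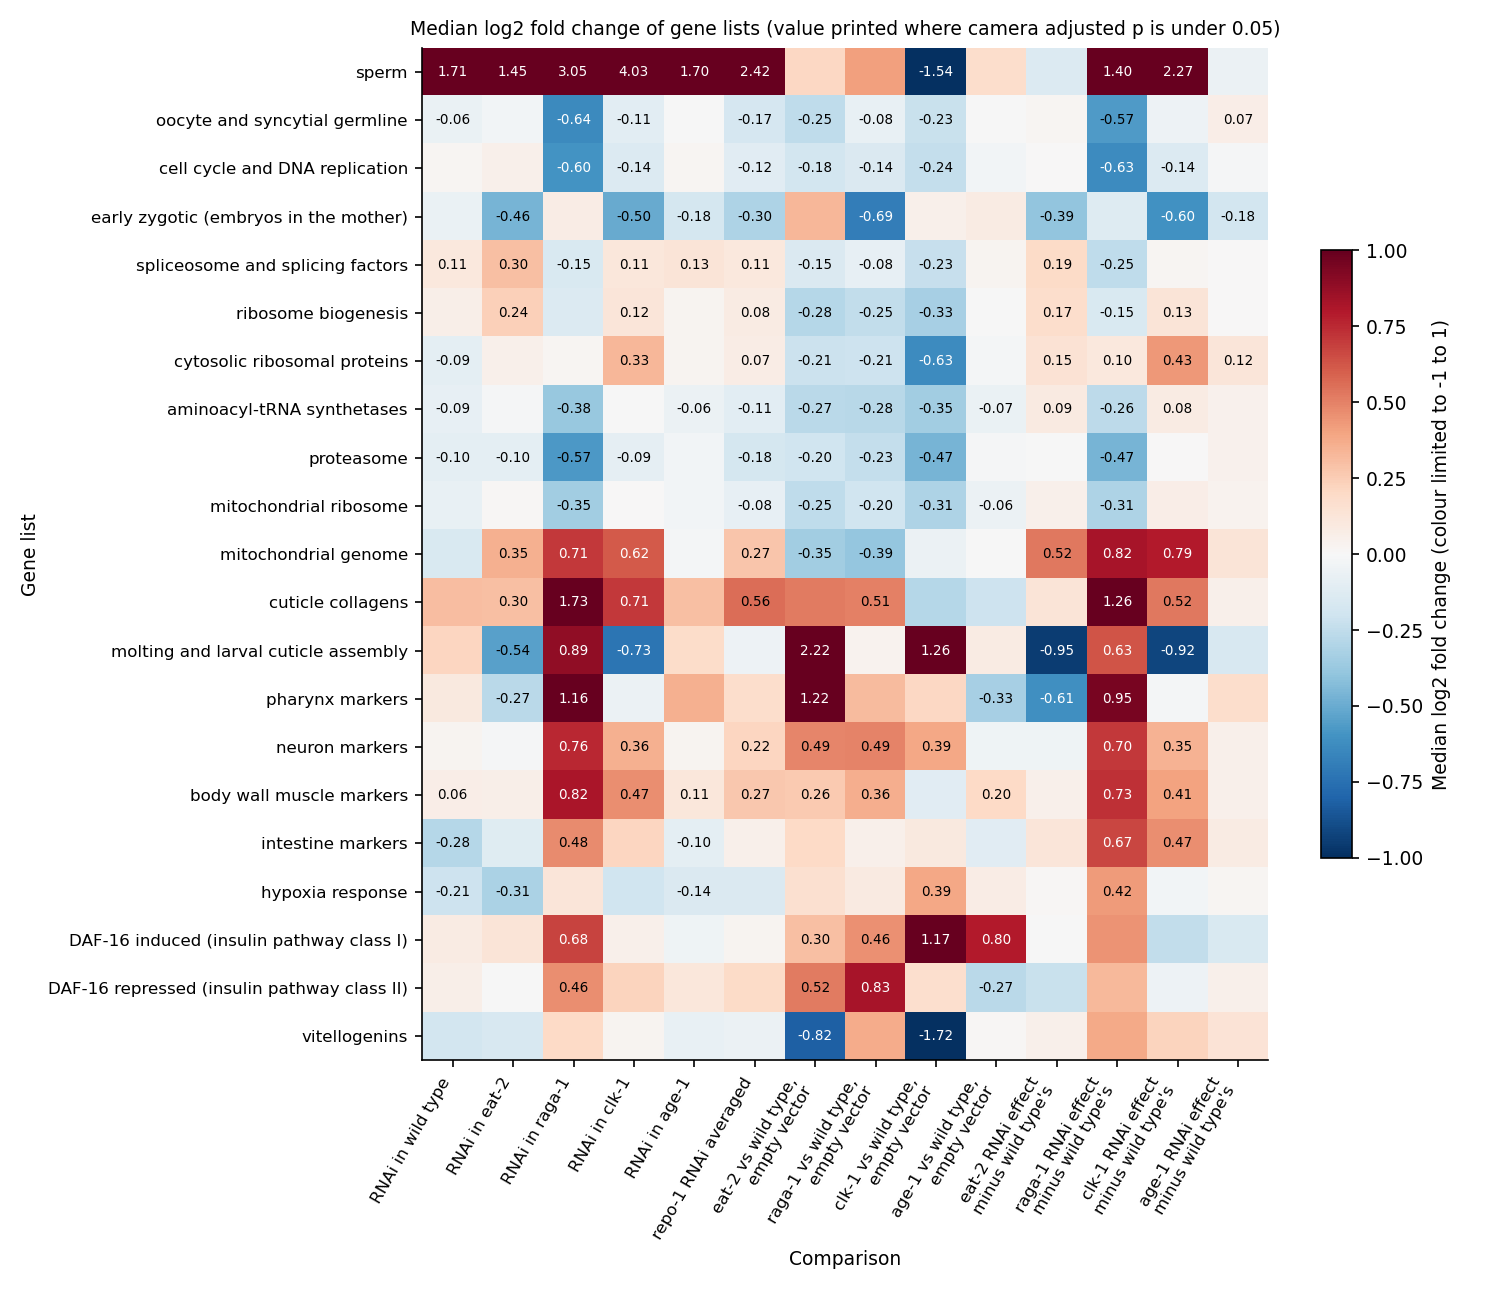
Median log2 fold change (colour, limited to -1 to 1) of 21 gene lists in the 14 comparisons, with the value printed where camera passed at the preset correlation. The sperm list has medians of 1.45 to 4.03 under repo-1 RNAi in the 5 genotypes.

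Lists of target of rapamycin and nutrient signalling components (25 genes), insulin pathway components (28 genes) and lipases and fat mobilization (18 genes) passed in none of the 14 comparisons by camera.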

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

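The tests for younger animals, for embryo genes, and for the share of germline and the scaling in raga-1 were chosen only after the results they address had been seen.

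Single libraries stood apart from the other 3 of their group in 7 of 80 groups of values checked by Dixon's test, where chance gives 4. They were vitellogenin reads in eat-2 repo-1 RNAi replicate 4 (10.8%, 95% Wilson interval 10.8 to 10.8%, against 9.33 to 9.56%) and in age-1 empty vector replicate 3 (14.1%, interval 14.1 to 14.2%, against 15.4 to 15.5%). The repo-1 transcript stood apart in wild type empty vector replicate 4 (889 against 815 to 826) and clk-1 empty vector replicate 4 (693 against 646 to 653). The eat-2 transcript did so in wild type empty vector replicate 1 (8.61 against 4.39 to 5.06) and eat-2 repo-1 RNAi replicate 2 (5.43 against 0 to 0.785), and clk-1 in wild type repo-1 RNAi replicate 1 (250 against 229 to 232).

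The response to repo-1 RNAi differed from that in wild type by the interaction test. In eat-2 it did so at 1320 genes, with cut-3 at -5.04, col-165 at -4.14, col-74 at -4.07, col-135 at 1.75, gpdh-1 at 1.41, ugt-26 at 1.08 and the SKN-1 detoxification list at a median of 0.236. In raga-1 it did so at 6852 genes, with msp-79 at 2.94, msp-56 at 2.62, acs-2 at 2.11, pigb-1 at -2.21, his-48 at -1.81, acdh-1 at -1.75, the cell cycle list at -0.626 and the neuron list at 0.704. In clk-1 it did so at 2908 genes, with msp-79 at 4.05, nspd-2 at 3.18, msp-81 at 2.97, cut-3 at -6.98, col-165 at -6.39 and col-74 at -6.28, and in age-1 the test called 1 gene, drd-50, for which chance was not excluded.

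Sperm genes rose under repo-1 RNAi in all 5 genotypes. The 23 tested members outside the msp, msd and nsp families had a median of 1.9 averaged over genotypes. Most of them bear ssp, ssq, smz or gsp names, which are families too, so this median cannot set aside reads shared within families. Of the others, spe-11 (2.4), sss-1 (1.98), fer-1 (1.31), spe-15 (0.718) and spe-4 (0.621) rose. In spe-41 (0.0822) and spe-5 (0.0941) the change was small. Shared reads are argued against for the genes that rose there, and stay open for the rest of the list. Males among the animals stay open, because 2 of 20 genes of male-specific cells were high enough to test, with a median of 0.366. Younger animals also stay open: the molting list had a median of at most -0.541 in eat-2 and clk-1, where embryo genes move that list the same way, and of at least 0.182 in the other genotypes. A change in how long hermaphrodites make sperm may also be the cause, and no biological explanation was tested.

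Germline lists fell and somatic lists rose under repo-1 RNAi in raga-1. A smaller share of germline alone would raise all body tissues alike, but the pharynx list rose above the intestine list by 0.536 (SD 0.141, n = 4), and the sperm list rose by 3.05. Scaling is argued against as the whole cause, with the oocyte list at -0.526 after quantile normalization, and so is the shallow raga-1 empty vector replicate 1, without which it was -0.632. A smaller germline together with other changes may remain, and was not tested.

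The molting list was higher on empty vector in eat-2 and in clk-1. A single pair of batches is argued against, as the lower of the medians in the 2 pairs was 1.83 in eat-2 and 1.17 in clk-1. Younger animals were predicted to raise the sperm list, which stood at -1.54 in clk-1, but the genotype may shift that list on its own. The vitellogenin list in clk-1, at a median of -1.72, moved as younger animals would move it. The share of all reads in vitellogenins differed less, at 13.4% in clk-1 and 15.2% in wild type. Younger animals therefore stay open in clk-1, and also in eat-2, where the sperm list stood at 0.209. More embryos in or among the animals is a candidate explanation, since 26 embryo genes outside the lists had medians of 1.56 in eat-2 and 1.2 in clk-1, among them dex-1 (2.19 and 1.61) and ceh-32 (1.67 and 1.46). Embryos held in the mother cannot be told apart from eggs or larvae carried over, and the embryo genes were listed after cut-3, hch-1 and hlh-1 had been seen.

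Other splits of the same libraries excluded chance at a share under 0.05 for the 9 comparisons of 2 groups and the averaged effect. For each of the 9 that share was 0.0286, the smallest that 35 splits can give, with no allowance for 14 counts. For the interactions the draws moved RNAi labels within each genotype and so broke the RNAi effect itself. They cannot decide whether 2 genotypes responded alike, and chance stays open for the interactions. Of 35 splits the real one alone gave as many genes, with 2839 against at most 9 in another split for RNAi in wild type, 4628 against 553 in eat-2, 8766 against 4564 in raga-1, 5708 against 2661 in clk-1 and 2572 against 1756 in age-1. The same held against wild type for eat-2 (7030 against 1589), raga-1 (5684 against 1235), clk-1 (7181 against 1730) and age-1 (1045 against 268). Of 100 draws 1 was as large for the averaged effect (8092 against 2803) and for the eat-2 interaction (1320 against 608). For the raga-1 and clk-1 interactions 2 were as large, the real one and another with 7121 and 2955 genes. In the former all 4 raga-1 RNAi labels stayed in place and those of wild type were nearly exchanged, so it holds the same raga-1 response. For the age-1 interaction 21 were as large as its 1 gene, with up to 2000, so chance was not excluded there either. In age-1 the split of batches 1 and 2 from batches 3 and 4 called 1303 genes under RNAi, which points to a structure of those libraries. Among the 8 splits that part all 4 numbered pairs, the real one alone was as large in each of the 9 comparisons of 2 groups. The smallest share that 8 splits can give lies above 0.05, so these splits alone cannot exclude chance. For RNAi in raga-1 another of them called 3825 genes.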

How the results depend on the processing

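The alternatives without the sperm list, without the cuticle collagen and molting lists, and without the 3 libraries of fewest reads were chosen after seeing the data.

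All 14 counts stayed within 1.5 times their value with no filter on low values, a mean of at least 50, pseudocounts of 0.5 and 8, quantile normalization, a replicate block and edgeR. Without the 3 shallowest libraries they did so too, with 3323 genes for RNAi in wild type and 1 for the age-1 interaction. The replicate block, which pairs libraries by number, called 1117 genes for age-1 against wild type, and it ended 3 list calls and gained 3.

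Fits to only the libraries of the groups compared gave 1067 genes for RNAi in age-1, 2219 for the eat-2 interaction and 0 for the age-1 interaction, where limma called 1 gene on all libraries, 695 genes had an unadjusted p under 0.05, edgeR called 1 and DESeq2 called 8. Fewer libraries set the error in these fits. Array quality weights gave 4460 for RNAi in wild type, 1638 for age-1 against wild type, and 2639, 4622 and 56 for the eat-2, clk-1 and age-1 interactions. The cause was not tested.

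Leaving out replicates gave 1679 (without replicate 4) to 2666 genes for RNAi in wild type and 1316 to 3077 for RNAi in age-1, with 1316 without replicate 3 and 1433 without replicate 2. For age-1 against wild type it gave 561 to 1313, with 590, 595 and 561 without replicates 1, 2 and 4 and 653 without age-1 empty vector replicate 1. For the eat-2 interaction it gave 696 to 1222, with 708, 773 and 696 without replicates 2, 3 and 4. For the clk-1 interaction it gave 1678 to 3029, with 1678 and 1908 without replicates 3 and 4. For the age-1 interaction it gave 0 to 4, with 4 and 0 without replicates 3 and 4, 2 without wild type repo-1 RNAi replicate 1 and 3 without age-1 empty vector replicate 3. These fits have fewer libraries.

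Of 672 list tests 269 passed at the preset correlation and 21 with a correlation estimated from the data, so most list calls rest on the preset value. After quantile normalization 262 passed, with 0 in the opposite direction by camera.

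The mutant effect kept under RNAi, as a fraction, was 0.473 in eat-2 with genes chosen at an adjusted p under 0.01 and 0.437 with no filter, and 0.644 in clk-1 with no filter. With no filter 1 exchange in raga-1 gave 0.757. In age-1 it turned to -0.45 and -0.72 under the same settings, where one exchange had 33 genes at the stricter threshold and a slope of -0.109 on empty vector. The agreement of the knockdown between genotypes, a median r of 0.495, was 0.463 without the sperm list.

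Of 2364 tests of named genes 2174 kept their direction and their side of the threshold after quantile normalization, 187 lost the call and 3 reversed: nhr-57 for RNAi in raga-1 (-0.02018), vit-4 for eat-2 against wild type (0.27) and pab-1 in the clk-1 interaction (-0.02865). Quantile normalization sets the values of the most abundant genes, such as vit-4, by their ranks alone, so it does not test their change. For the other genes the cause was not tested. The numbers kept were 2263 with edgeR, 2339 with a pseudocount of 8, 2353 with the block, and 2091, 2059, 2060 and 2068 without replicates 1 to 4. Depth limits the lowest transcripts, such as eat-2, whose group means of 1.55 to 12 kept it out of the tests.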

Other observations

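The tests for embryo genes were chosen only after the results had been seen.

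The intracellular pathogen response, a set of pals and F-box genes induced by microsporidia and viruses, was higher on empty vector in eat-2 and in clk-1. It rose in eat-2 in 14 of 20 members and fell in 1 (the same adjusted over the list alone), with a median of 0.784 (0.356 after quantile normalization) and pals-37 at 2.6 ± 0.5 (camera adjusted p = 0.00388, and adjusted p = 0.0929 with an estimated correlation). In clk-1 it rose in 13 members and fell in 1 (the same adjusted over the list alone), with a median of 0.652 (0.311 after quantile normalization, at camera adjusted p = 0.05) and pals-6 24-fold higher (4.58 ± 0.339) (camera adjusted p = 0.0055, and adjusted p = 0.0975 with an estimated correlation). Intestinal immune genes rose in eat-2 in 28 of 47 members and fell in 3 (29 and 4 adjusted over the list alone). The median was 0.705, with the lysozyme lys-7 at 1.94 ± 0.159 (camera adjusted p = 2e-06, and adjusted p = 0.0994 with an estimated correlation).

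Genes of one-carbon metabolism and phosphatidylcholine synthesis fell in clk-1 on empty vector in 14 of 23 members and rose in 2 (the same adjusted over the list alone). The median was -0.294, with the S-adenosylmethionine synthetase sams-1 at -1.54 ± 0.0868 (camera adjusted p = 0.0022, and adjusted p = 0.0564 with an estimated correlation). Glucuronosyltransferases, which conjugate lipophilic compounds, were higher in the raga-1 interaction in 38 of 52 members (38 up and 1 down adjusted over the list alone). The median was 0.725, with ugt-53 at 2.26 ± 0.416 (camera adjusted p = 5.47e-07, and adjusted p = 0.051 with an estimated correlation).

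Genes of the middle and late embryo, 26 of them measured outside the fixed lists, also moved under repo-1 RNAi. Of these 12 fell and 1 rose in eat-2 (median -0.443), and 16 fell and 1 rose in clk-1 (median -0.751), the genotypes in which the set was higher on empty vector. In wild type 6 rose (median 0.23), and in age-1 2 rose (median 0.0629). In raga-1 13 rose and 2 fell, with a median of 0.597 that was -0.0818 after quantile normalization. The set's median difference from the wild type response was -0.974 in eat-2 and -1.42 in clk-1. Fewer embryos under RNAi in eat-2 and clk-1 is a hypothesis that rests on the same genes as the medians of 1.56 and 1.2 on empty vector, and was not tested separately.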
